A study of Mus musculus with 5 samples.

How the data were processed

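The series compared cortical tissue of wild-type mouse embryos at embryonic day 14.5 (E14.5), with 3 libraries of the medial cortex and 2 of the lateral cortex. Per the labels' protocols, tissue was dissected from brains of a mixed strain background, RNA was extracted with a column kit for small samples, and libraries were made from polyadenylated RNA without marking the strand. Reads of a gene and of an overlapping or antisense gene therefore cannot be told apart where their exons overlap. Nothing in the labels says whether the replicates came from separate embryos, so p-values measure only the spread between these samples.

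The deposited files hold 1 count per gene symbol, as whole numbers of reads that the authors did not normalise, for 34590 symbols. The submitters' processing notes name the mouse build mm9 and the tools BWA, STAR and HTSeq, without versions, order or roles. The files also hold 5 classes of reads that HTSeq assigned to no gene. These classes made up between 23.1% and 28.7% of each file's total and were kept out of library sizes and tests. The remaining gene counts came to 27406370, 27993560 and 36460274 in medial libraries 1 to 3 and to 66981952 and 56147129 in lateral libraries 1 and 2. A floor of 3 reads corresponds to between 0.0448 and 0.109 CPM, and intervals and floors cover counting error only. No annotation of mm9 was used here, so no positions are given, and gene symbols stand as the files give them.

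Groups were taken from the labels. Counts were normalised with TMM and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest), with group as the only term and 3 residual degrees of freedom. The form of the test introduced with edgeR 4 was set explicitly, because this version otherwise uses the older form. This was settled before any result was seen. Genes were kept by filterByExpr with the groups and its defaults of a count of 10 and a total of 15, which left 16229 genes. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. Fold changes are medial over lateral on the log2 scale. Their standard error (SE) is the log2 fold change divided by the root of the F statistic. Levels are TMM-normalised read counts scaled to library size (CPM), as mean and SD over 3 medial or 2 lateral libraries.

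A set of 36 gene lists for pathways, cell types and sample quality, the rule for the named genes, the tests and most alternatives were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. They were tested again with an estimated correlation and with fry, which asks only whether the genes of a list move on balance in one direction. Adjustment ran over the 36 lists. Counts of list members past the gene-level threshold are given over all genes tested and adjusted over the list alone. The rule for named genes took 17 anchor genes whatever their result. It added the 10 genes with the largest fold each way among those past the threshold with a mean of at least 1 CPM and no overlap between groups, leaving out unnamed gene models. From each list it took up to 4 members past the threshold with the lowest adjusted p, or up to 2 with the highest mean where none passed. Genes named outside this rule were chosen after their values were seen and are marked as such. Some genes taken by the rule are not reported here.

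The test was checked on 4 simulated sets with the means, dispersions and library sizes of the real libraries and 200 changed genes each, over between 15991 and 16032 genes. At 3 against 2 libraries, edgeR recovered 46.5% of the genes changed 2-fold and 85.5% of those changed 4-fold. Of its 610 calls, 82 (13.4%) were false, which is more than the threshold of 0.05 implies. DESeq2 recovered 65% and 88.5%, with 30.6% of its 885 calls false. The share of false calls depends on how many genes change, so these shares do not carry over to the real comparison. With no gene changed, edgeR made 1 call. In a simulation of lists, camera called the list of 20 genes raised 2-fold and 0 of 20 lists of unchanged genes. The genes were simulated independently of each other, while the correlations estimated in the real lists ranged from −0.04 to 0.83. The simulation therefore does not show how camera with the preset correlation behaves on correlated genes.

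Alternatives covered DESeq2 size factors, upper-quartile scaling and library size alone in place of TMM, and DESeq2 1.42.0, the older and the robust edgeR tests and limma-voom in place of the main test. They also covered no low-count filter, filters at 1 and 5 CPM in 2 libraries, thinning to the smallest library, leaving out each library, and blocks by replicate number or by a tag in the deposited names. Leaving out each library with DESeq2, counting list members without each library, and testing the hedgehog response list without medial library 1 by the other list tests were added after the data were seen. No pair of libraries matched within sampling noise: the chi-square statistic per degree of freedom was at least 24.6 in each of the 10 pairs.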

Results

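Gene expression was measured by RNA sequencing in the medial and the lateral cortex of wild-type mouse embryos at E14.5, a stage at which radial glia divide and intermediate progenitors form. There were 3 medial and 2 lateral libraries. Gene counts ranged from 27406370 to 36460274 in the medial libraries and from 56147129 to 66981952 in the lateral ones, so depth differed with region. The series title names Sonic hedgehog signalling, basal radial glia and intermediate progenitors, and its design names the single comparison of medial with lateral cortex.

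The genes with the largest differences toward medial cortex included Wnt ligands and R-spondins, secreted potentiators of Wnt signalling. In these families, which were chosen after the results were seen and not tested as groups, 6 of 10 tested Wnt genes and 2 of 3 R-spondin genes were higher, and 1, Wnt7b, was lower. Wnt8b, a ligand of the cortical hem, averaged 56.5 CPM ± 52.5 (SD, n = 3) in medial and 0.125 ± 0.124 (SD, n = 2) in lateral libraries, a log2 fold change of 8.70 (SE 1.29). Under the rule for named genes the next were Lect1 (log2 fold change 8.09), Rspo1 (7.05), Wnt3a (6.86), Rspo2 (6.80), the extracellular matrix genes Lox (6.68) and Prelp (6.46), the zinc-finger factor Sp5 (6.15), Mir135a-2 (6.09) and the retinol carrier Rbp4 (5.88). Medial library 1 carried part of these values. Without it the log2 fold change was 7.60 for Wnt8b, 5.99 for Wnt3a, 5.93 for Rspo2, 5.55 for Lox, 5.18 for Sp5 and 5.05 for Rbp4, and each kept its call. Mir135a-2, with 0.0912 and 0 CPM in the lateral libraries, ranged from 5.25 to 10.05 over all alternatives. In lateral cortex the largest differences were in the transcription factor Prdm12 (−4.34), the urea transporter Slc14a1 (−3.87), the heparan sulfate enzyme Hs3st3b1 (−3.75), the melanocortin receptor Mc4r (−3.71), the adhesion molecule Ntm (−3.68) and the upper-layer factor Pou3f1 (−3.50). Single libraries moved these values too: over all alternatives Prdm12 ranged from −5.70 to −3.82, Slc14a1 from −4.90 to −3.08, Mc4r from −4.74 to −2.97, Ntm from −4.18 to −2.93 and Pou3f1 from −4.30 to −3.20. Of the 99 genes that the rule took and that passed, 29 changed their fold by more than 1.5 times when 1 library was left out, 12 of them without lateral library 2 and 10 each without medial library 1 and medial library 3.

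Of 16229 genes tested, 1577 passed the threshold in edgeR, 750 higher in medial and 827 higher in lateral cortex, and 382 and 383 of these differed at least 2-fold. The smallest adjusted p was 0.0104. The groups did not overlap in 53.3% of the genes tested, against 20% expected if libraries were exchangeable. Genes vary together and no other split of the libraries was counted, so this contrast does not measure evidence for region. Lect1, higher in medial cortex, had 282 medial reads and 1 lateral read, a ratio of 378 with a 95% exact interval from 67.3 to 14982. Mir135a-2 is a microRNA gene, and polyA libraries count reads over its locus, not the mature RNA. The calls depended on single libraries. Leaving out medial library 2 or lateral library 2 left 0 calls in edgeR, with 4035 and 2456 genes at an unadjusted p under 0.05 and 2006 and 664 calls in DESeq2. Leaving out lateral library 1 left 18 calls and medial library 3 490, while 2164 genes passed without medial library 1, 1027 higher in medial and 1137 higher in lateral cortex. In each of these 5 fits all of the called genes that were tested, 1576 or 1577, kept their direction. Each fit reused libraries of the fit that chose these genes, so this was close to fixed beforehand and adds no support.

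**Figure D1:**
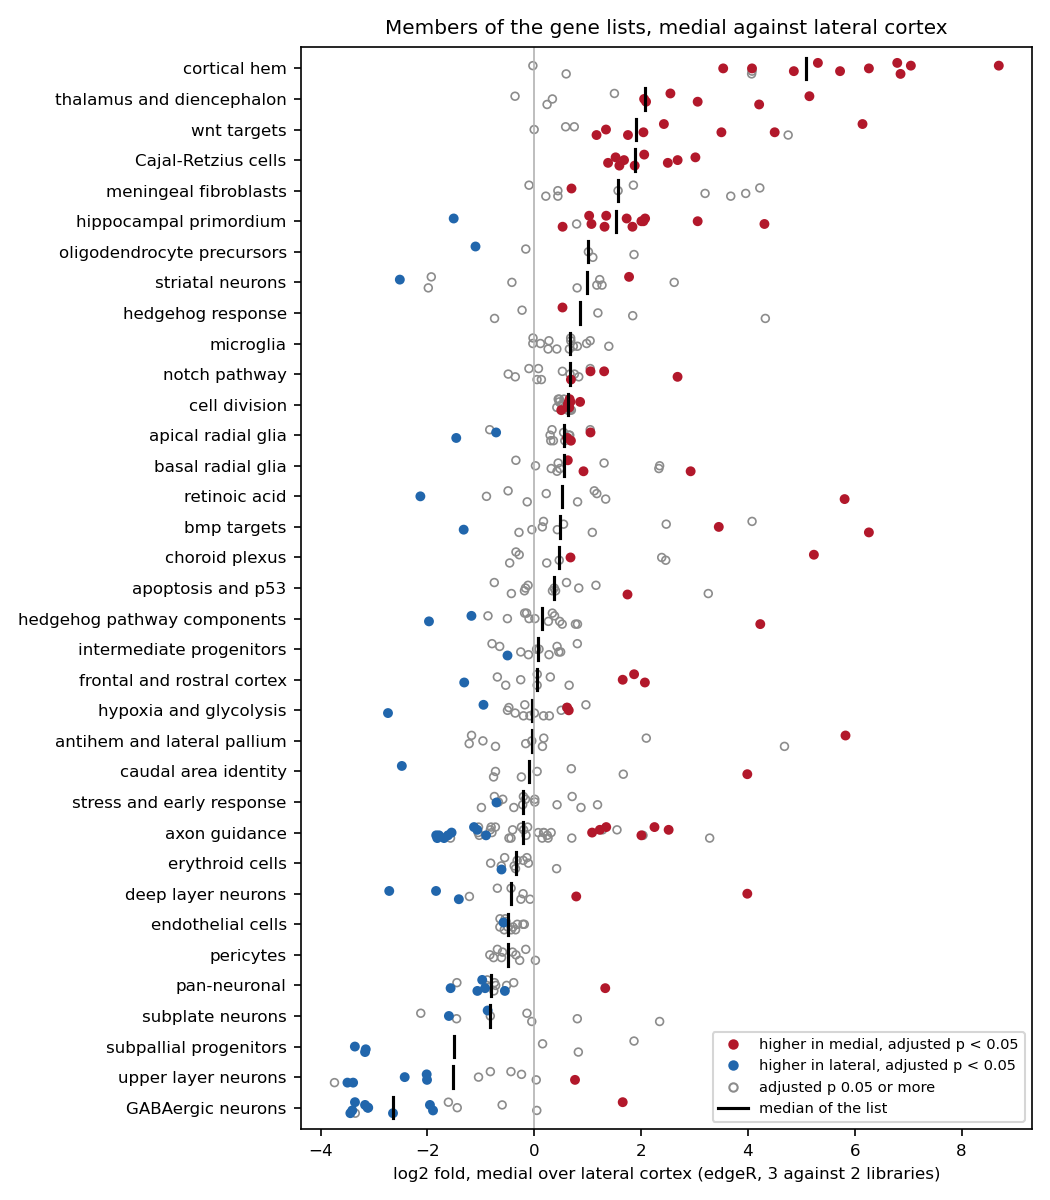
Each point is a gene of a list fixed before the data were examined. The horizontal axis gives its log2 fold change, medial over lateral cortex, from edgeR with 3 and 2 libraries, filled points passed an adjusted p of 0.05, and black lines are list medians. The cortical hem list has a median of 5.09 and the GABAergic list a median of −2.65.

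Genes of the medial edge of the cortex were higher in medial libraries. Of 14 tested genes of the cortical hem, the signalling centre at the medial edge, 10 were higher and 0 lower (12 adjusted over the list alone), among them Bmp7 (log2 fold change 3.54, SE 0.22) and Wnt5a (4.08, SE 0.37). In the hippocampal primordium list 12 of 14 were higher (13 adjusted over the list alone), among them the receptor Ephb1 (2.01), the Wnt effector Lef1 (2.04), Nrp2 (1.35), Dmrt3 (1.73) and Emx2 (1.32, SE 0.18), while Wnt7b, named after its value was seen, was lower (−1.51). Of 12 Wnt target genes, 8 were higher (10 adjusted over the list alone), with Axin2, a feedback inhibitor, at 91.0 CPM ± 13.9 (SD, n = 3) against 26.9 ± 1.97 (SD, n = 2), and with Tnfrsf19 (2.43) and Rnf43 (3.50). All 9 tested genes of Cajal-Retzius cells, early neurons that secrete reelin, were higher, also over the list alone, with Reln at 491 CPM ± 61.0 (SD, n = 3) against 163 ± 25.8 (SD, n = 2), Cacna2d2 at a log2 fold change of 1.68, Trp73 at 2.50 and Lhx1 at 3.02. In the list for thalamus and diencephalon 6 of 10 were higher (7 adjusted over the list alone). Among these were Zic1 (4.21), Zic2 (2.09), Zic4 (5.15), Zic5 (2.55) and Lhx9 (3.06), of which Zic2 and Zic4 were named after their values were seen. These Zic genes are also expressed in medial forebrain, and Lhx9 is also in the hippocampal list. Without medial library 1 the log2 fold change of Zic4 was 3.91.

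Camera gave adjusted p-values of 4.2e-09 for the hem, 1.4e-07 for the hippocampal primordium and for Wnt targets, 1.2e-09 for Cajal-Retzius cells and 5.4e-05 for the thalamus list. Each of these 5 had an adjusted p = 0.597 with an estimated correlation, and over all alternatives that was the highest value for each. In that form of camera 0 lists passed. Its lowest unadjusted p was 0.0192, for Cajal-Retzius cells, of which 9 of 9 genes passed singly. The correlation was estimated with 3 residual degrees of freedom, so failing this form sets no list apart, here or below. The same 5 lists were the ones that passed with fry, at adjusted p-values of 0.0282, 0.0281, 0.0281, 0.0063 and 0.0281. Medial library 1 stood above the others here: 10 of the 15 listed hem genes were at least 2-fold higher in it than in any other library, with Wnt8b at 117 CPM against 30.5 and 22.1 in medial libraries 2 and 3. Without it, 12 of 14 hem genes, 12 of 14 hippocampal genes, 8 of 11 Wnt targets, 9 of 9 Cajal-Retzius genes and 6 of 10 genes of the thalamus list were higher in medial cortex.

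Among 12 BMP target genes Id3 (log2 fold change 3.45) and Msx2 were higher and Id2 was lower (−1.32), with 3 higher and 1 lower adjusted over the list alone and a camera adjusted p of 0.0788. Msx2 had 80 medial reads and 1 lateral read, a ratio of 107 with a 95% exact interval from 18.7 to 4288, and without medial library 1 its log2 fold change moved from 6.27 to 5.67. In the choroid plexus list Otx2 (5.24) and the ciliary factor Foxj1 (0.68) were higher of 9 tested (4 adjusted over the list alone), and the list had an adjusted p of 0.0985. Without medial library 1 the log2 fold change of Otx2 was 4.29. Ttr, the most abundant transcript of choroid plexus, stayed between 0.659 and 10.4 CPM in every library and is named here after its values were seen.

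Genes of dividing cells and of radial glia were higher in medial cortex as lists by camera at its preset correlation, but not with an estimated correlation or with fry (adjusted p = 0.107 for each of these lists). The intermediate progenitor list did not pass. All 24 tested genes of cell division had positive log2 fold changes with a median of 0.63. Of these, 10 passed over all genes and 24 adjusted over the list alone, among them Aurka (0.63, SE 0.10), Rrm2 (0.63), Tyms (0.68) and Aurkb (0.64). Of 12 basal radial glia genes, which mark progenitors that have left the ventricular surface, 3 were higher (7 adjusted over the list alone). They were Hopx, at 34.3 CPM ± 22.8 (SD, n = 3) against 4.50 ± 0.232 (SD, n = 2), and the cytokine receptor genes Il6st (0.92, SE 0.14) and Lifr (0.63, SE 0.11). Tnc, a matrix protein of these cells, had a log2 fold change of 2.33 (SE 0.79, adjusted p = 0.107). Hopx also marks the medial wall in the embryo, and which cells held its RNA in these libraries was not tested.

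In the apical radial glia list 3 of 16 were higher, Hes1 (log2 fold change 1.05), Nes (0.62) and Notch1 (0.69), and 2 were lower, Ddah1 (−0.72) and Ednrb (−1.46), with 8 higher and 2 lower adjusted over the list alone. Pax6 (0.31, adjusted p = 0.132) and Sox2 (0.64, adjusted p = 0.111) did not pass, but with a block by a tag in the deposited names they did, as did Tnc (adjusted p = 0.0160, 0.0046 and 0.0025). Sox2 also passed with a block by replicate number and with DESeq2. The Notch list had 4 of 15 higher (7 adjusted over the list alone), Hey2 (2.68, SE 0.30), Hes1, the glycosyltransferase Lfng (1.31) and Notch1. Among 12 intermediate progenitor genes 0 were higher and 1, Elavl4, was lower (−0.50, SE 0.08), with 2 higher and 3 lower adjusted over the list alone. With the block by tag 5 were higher and 3 lower, and with DESeq2 2 were higher and 3 lower. Eomes, the defining factor of these cells, had 305 CPM ± 34.2 (SD, n = 3) against 329 ± 39.0 (SD, n = 2) and a log2 fold change of −0.11 (SE 0.13, adjusted p = 0.595), and Neurog2 one of 0.04 (SE 0.20, adjusted p = 0.902).

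The camera adjusted p was 2.4e-09 for cell division, 0.0181 for basal radial glia, 0.0252 for apical radial glia and 0.0240 for Notch. The values were adjusted p = 0.597 with an estimated correlation for the first 2 lists and adjusted p = 0.612 with an estimated correlation for the others. The intermediate progenitor list had an adjusted p of 0.905, with a positive median of 0.07 and mean of 0.02 although camera gave the downward direction. Medial library 1 held 60.6 CPM of Hopx and 136 CPM of Tnc, against at most 22.2 and 40.8 in any other library. Without it, 12 cell division genes, 4 basal and 5 apical radial glia genes, 5 Notch genes and 1 intermediate progenitor gene were higher in medial cortex, and Hopx kept its call while its log2 fold change moved from 2.93 to 2.23. In the same fit the intermediate progenitor genes Elavl4 (−0.46) and Sstr2 (−0.52), the latter named after its value was seen, were lower. The apical genes Ddah1 (−0.64) and Ednrb (−1.20) were lower there too. Leaving out medial library 3 ended the camera calls of the apical radial glia and Notch lists, and the apical list also lost its call without lateral library 2, with library size alone as scaling and with a block by replicate number. The basal list lost its call with a block by a tag in the deposited names (0.0709).

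The upper-layer and pan-neuronal lists were lower in medial cortex by camera at its preset correlation, but not with an estimated correlation or with fry. Of 12 upper-layer genes 5 were lower in medial libraries (9 adjusted over the list alone), among them Cux2 at 18.7 CPM ± 5.63 (SD, n = 3) against 101 ± 42.4 (SD, n = 2), Pou3f1 (log2 fold change −3.50), Pou3f2 (−2.02) and Rorb (−2.01), the last named after its value was seen. Lmo4 was higher (0.76, SE 0.08). Of 14 pan-neuronal genes 5 were lower (11 adjusted over the list alone), including Syt1 (−1.57, SE 0.25), Rbfox3 (−0.55) and Dcx (−0.92), while the neurofilament gene Nefl was higher (1.33, SE 0.21). In the deep-layer list Tbr1 (−1.41, SE 0.32), Sox5 (−1.84) and Ldb2 (−2.72) were lower and Crym (3.99) and Zfpm2 (0.79) higher of 11 (5 lower and 2 higher adjusted over the list alone). The subplate genes Nxph3 (−1.60) and Tmem178 (−0.87) were lower of 9, the same count adjusted over the list alone.

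The list for GABAergic neurons, which migrate into the cortex from the ventral forebrain, was also lower by camera at its preset correlation only. Of 15 tested genes, 9 were lower in medial cortex (13 adjusted over the list alone), with the GABA-synthesising enzymes Gad1 at 0.892 CPM ± 0.709 (SD, n = 3) against 10.2 ± 1.93 (SD, n = 2) and Gad2 at 1.04 ± 0.882 (SD, n = 3) against 11.6 ± 3.69 (SD, n = 2). Sp8, which is also a gene of the medial and rostral cortex, was higher (1.66, SE 0.26). The subpallial progenitor list had 3 of 6 lower, Dlx1 (−3.16), Dlx2 (−3.36) and Sp9 (−3.17), the last shared with the GABAergic list, and 1 higher and 3 lower adjusted over the list alone. Over all alternatives Dlx1 ranged from −4.10 to −2.75, Dlx2 from −4.69 to −2.97 and Sp9 from −4.61 to −2.80. Dlx1 reads cannot be told apart from those of its antisense gene. In the striatal list 1 of 10 was higher and 1, Drd1a, lower (−2.52), with 5 higher and 3 lower adjusted over the list alone.

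Camera gave adjusted p-values of 6.9e-05 for GABAergic, 0.00155 for upper-layer and 0.000356 for pan-neuronal genes. The first 2 had an adjusted p = 0.597 with an estimated correlation and the last an adjusted p = 0.612 with an estimated correlation. Deep-layer (0.139), subplate (0.110), subpallial (0.325) and striatal (0.373) lists did not pass. Without medial library 1, 9 GABAergic, 6 upper-layer and 7 pan-neuronal genes were lower in medial cortex. The lateral libraries also held more reads in total, and 1498 genes passed with all libraries thinned to the smallest.

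**Figure D2:**
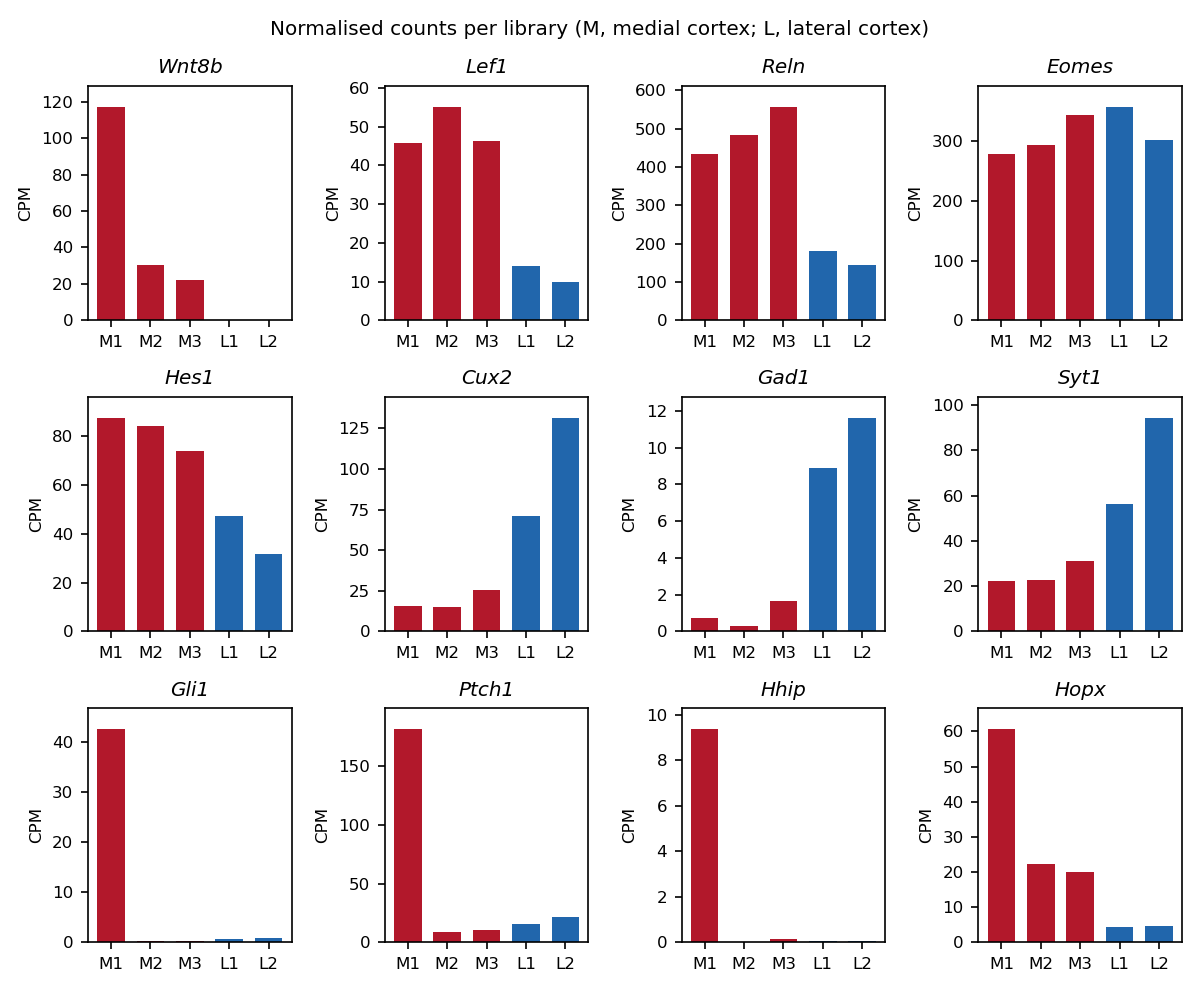
Bars give the TMM-normalised read counts (CPM) of 12 genes in the 3 medial libraries (M1 to M3) and the 2 lateral libraries (L1 and L2). Gad1 and Cux2 are higher in each lateral library than in any medial one, and Gli1 reaches 42.4 CPM in M1 against at most 0.799 in the others.

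Hedgehog response genes did not pass as a group between the regions, and 4 of the 9 listed, among them Gli1, Ptch1 and Hhip, were at least 2-fold higher in medial library 1 than in any other library. Gli1, a transcription factor induced by hedgehog signalling, had 42.4 CPM (1223 reads) in medial library 1 and between 0.245 and 0.799 CPM in the others. Ptch1, the receptor induced by the same signal, had 181 CPM there and between 9.09 and 21.9 CPM elsewhere. Hhip, a hedgehog-binding protein that the filter left out because it had enough reads in only 1 library, had 270 reads there and at most 5 in any other library. Shh itself had 0 medial and 6 lateral reads. A count of 0 allows up to 0.109 CPM in the shallowest library.

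Over all libraries Gli1 had a log2 fold change of 4.33 (SE 2.19, adjusted p = 0.230) and Ptch1 one of 1.84 (SE 1.37, adjusted p = 0.402). Mycn was the only 1 of 6 tested response genes that passed, higher in medial cortex (0.52, SE 0.09), with 1 higher and 1 lower adjusted over the list alone. Camera gave an adjusted p of 1.00 in the downward direction, although the median was 0.85 and the mean 1.15. Without medial library 1 the list was lower in medial cortex by camera at its preset correlation (adjusted p = 0.0151, with a range from 0.0109 to 1.00 over all alternatives), and 3 of 6 genes were lower. The list did not pass in that fit with an estimated correlation (0.591), where 0 lists passed, or with fry (0.0977), where 3 did. Both tests were chosen after the results were seen. Ptch1 then had a log2 fold change of −0.94 (SE 0.20, adjusted p = 0.0402, range 3.3e-05 to 0.833) and Gli1 one of −1.18 (SE 0.38, adjusted p = 0.0989, range 0.0197 to 0.771).

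Of 16 hedgehog pathway components, Scube1 (log2 fold change −1.97, SE 0.43) and Disp2 (−1.18, SE 0.26) were lower in medial cortex, and the endocytic receptor gene Lrp2 was higher (4.23, SE 0.96). Lrp2 had 24.9 CPM in medial library 1 against 6.78 and 4.37 in medial libraries 2 and 3, and without library 1 its log2 fold change was 3.13 (SE 0.34). Adjusted over the list alone 4 were higher and 2 lower. The transducer Smo (0.77, SE 0.20, adjusted p = 0.0631) and the transcription factor Gli3 (0.38, SE 0.11, adjusted p = 0.0817) did not pass, and camera gave 0.536 for the list. Smo passed in 3 and Gli3 in 2 of 18 alternatives, with the lowest adjusted p (0.00018 and 0.0063) under the block by tag, where 8 of the 16 were higher and 4 lower.

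Medial library 1 also stood apart in other genes, all named here after their values were seen. By a rule of at least 5 CPM and at least 4 times the level of each other library, 47 genes were raised in it and 0 in each of the other 4 libraries. Prm1, which encodes a sperm protamine, had 3044 reads in medial library 1, 1 read in lateral library 1 and 0 in the other 3. Fgf15 had 29.0 CPM against at most 0.390, Col1a1 97.2 against at most 4.62 and Olig2 16.2 against at most 1.82. Medial library 1 had 103 CPM of the Y-linked gene Ddx3y and 6.52 CPM of Xist, and the other libraries with Ddx3y, medial 2 and lateral 1, had 0.560 and 0.365 CPM of Xist. Medial library 3 and lateral library 2 had 260 and 266 CPM of Xist and 0.0556 and 0.0557 CPM of Ddx3y. The strand-blind counts do not separate Xist from its antisense gene. The label of medial library 1 reads wild type, as do those of the others.

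**Figure D3:**
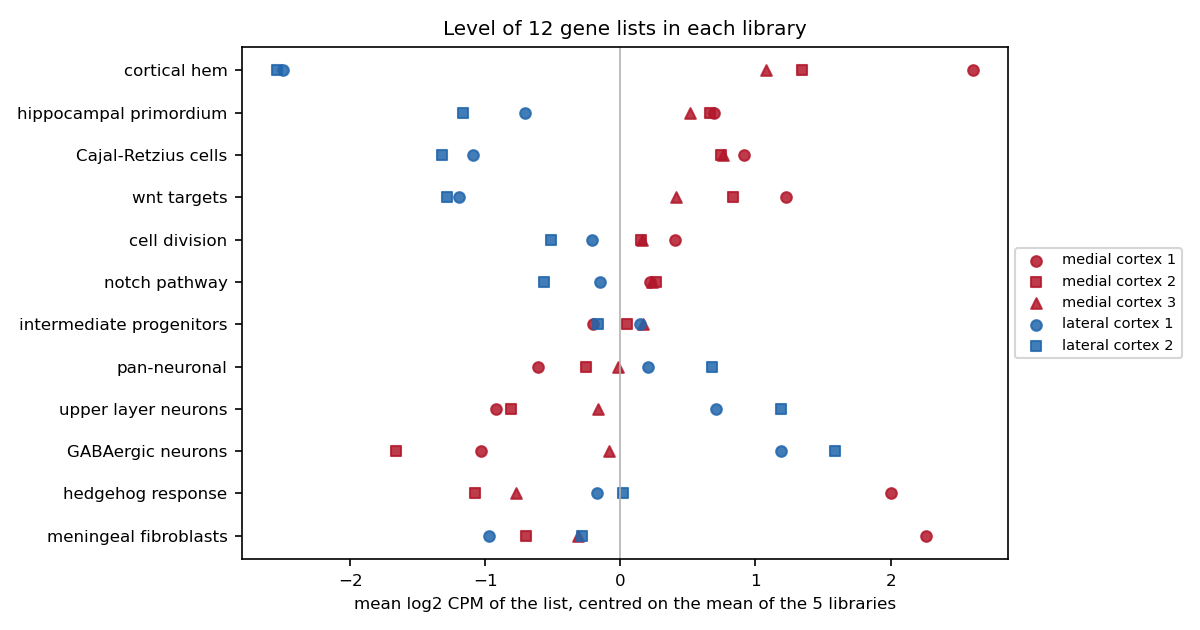
Each symbol is the mean log2 CPM of a gene list in a library, centred on the mean of the 5 libraries. Medial library 1 (red circles) lies highest for the cortical hem at 2.61, and at 2.01 for the hedgehog response and 2.26 for the fibroblast list it lies apart from the 4 other libraries.

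Regional lists for other parts of the cortex were split. In the list for the antihem and lateral pallium 1 of 11 passed, Cyp26b1, an enzyme that degrades retinoic acid (log2 fold change 5.81, SE 0.34), higher in medial cortex (1 higher and 2 lower adjusted over the list alone). Its camera adjusted p was 0.825, downward, with a median of −0.05 and a mean of 0.78. In the retinoic acid list 1 of 10, Cyp26b1, was higher and 1 lower (1 higher and 2 lower over the list alone, camera 0.649). Of 11 frontal genes Sp8, Etv4 (1.87) and Spry1 (2.07) were higher and Fgf18 (−1.31) lower (3 higher and 2 lower over the list alone, camera 0.702). Of 8 genes of caudal identity Crym was higher and Cdh8 lower (−2.48), with 2 higher and 1 lower over the list alone, a camera adjusted p of 0.962 downward, a median of −0.09 and a mean of 0.27. Sfrp2 had a log2 fold change of 0.15 (SE 0.15, adjusted p = 0.541). Among 42 axon guidance genes 6 were higher, including Slit2 (2.52, SE 0.24), Ephb1 and Nrp2, and 9 lower, including Nrp1 (−1.07, SE 0.11), with 11 and 13 over the list alone and a camera adjusted p of 0.472.

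The vascular lists were lower in medial cortex by camera at its preset correlation. All 13 endothelial genes had negative log2 fold changes with a median of −0.50 and a camera adjusted p of 2.9e-05 (adjusted p = 0.597 with an estimated correlation), and 1, Cdh5 (−0.58, SE 0.11), passed (8 adjusted over the list alone). Pericyte genes, with Rgs5 at −0.61 (adjusted p = 0.116) and Pdgfrb at −0.27 (adjusted p = 0.310), had 0 of 10 calls by either adjustment and a camera adjusted p of 0.0176 (adjusted p = 0.655 with an estimated correlation). That call was lost without medial library 2, without lateral library 2, with the 5 CPM filter and with a block by replicate number. The microglial genes Cx3cr1 (0.73, adjusted p = 0.209) and Csf1r (0.42, adjusted p = 0.348) did not pass, with 0 of 14 calls by either adjustment and a camera value of 0.0964. Medial library 1 carried part of this rise. The centred mean log2 CPM of the list was 0.81 there against −0.13 and −0.10 in medial libraries 2 and 3. Without it the log2 fold change of Cx3cr1 was 0.34.

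Of 11 erythroid genes Hbb-y was lower (−0.62), also over the list alone. The camera value was 0.0596, and the list passed downward in 7 of 16 alternatives (range 0.00081 to 0.655), among them the fit without medial library 1, where 5 genes were lower. Of 5 oligodendrocyte precursor genes Sox8 was lower (−1.11), also over the list alone, and the camera value was 0.588 downward with a median of 1.01 and a mean of 0.54. Without medial library 1 all 5 had negative log2 fold changes, with a median of −0.73, and the list passed downward there and with a block by the tag in the deposited names (range 0.0199 to 0.978 over all alternatives). The BMP target, choroid plexus, fibroblast and microglial lists each passed upward in 3 of 16 alternatives, and the subplate list downward in 1. Of 11 fibroblast genes Serpinh1 was higher (0.68), also over the list alone (camera 0.148), and 12 of the 16 listed were at least 2-fold higher in medial library 1 than in any other. Among quality lists Cyr61 was lower (−0.73) of 15 stress genes (2 higher and 4 lower over the list alone, camera 0.244) and Cdkn1a higher (1.73) of 13 apoptosis genes (4 higher and 1 lower, camera 0.228). Of 16 hypoxia and glycolysis genes Ldha (0.61) and Eno1 (0.65) were higher and Pfkp (−0.95) and Ndrg1 (−2.74) lower, with 3 higher and 3 lower over the list alone. That list had a camera adjusted p of 1.00 upward, a median of −0.04 and a mean of −0.11. Of 5 sex-linked genes 0 passed by either adjustment (camera 0.825).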

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

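The DESeq2 counts without single libraries, and the estimated correlation and fry without medial 1, were tests chosen after the results were seen. Replacing TMM by DESeq2 size factors, upper-quartile scaling or library size gave between 1572 and 1587 calls, with 53.1% of them higher in medial under the last 2 against 47.6%, and library size alone moved the median log2 fold change to 0.08. DESeq2 called 3527 genes (1737 higher in medial and 1790 higher in lateral), of a test whose simulated calls were 30.6% false. Of the 1577 calls of the main edgeR fit, 765 differed at least 2-fold. Without a low-count filter 1202 of 29303 genes passed, 496 higher in medial and 706 higher in lateral. Depth limits genes near the floor of 0.109 CPM in the shallowest library.

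Replicate numbers were not taken as pairs. Over genes, the deviation of lateral 1 correlated at 0.03 with that of medial 1, 0.38 with medial 2 and −0.38 with medial 3, and that of lateral 2 is its mirror image and adds no evidence. A block by these numbers, with 1 residual degree of freedom, gave 1076 calls, 454 of them higher in medial. Tags in the deposited names, a hint and not a label, pair lateral 1 with medial 2 and lateral 2 with medial 3. Sex, genes detected and olfactory receptor reads go with the tags. This crossed pairing as a block, also with 1 residual degree of freedom, gave 5361 calls (2634 and 2727). It leaves medial 1 without a partner and so out of the contrast. Leaving medial 1 out without a block gave 2164 calls, so that step alone did not give the 5361. Under the block by tag the hedgehog response list was lower in medial (camera adjusted p = 0.0109), the basal radial glia list did not pass (0.0709), and Gli1 (−1.22), Ptch1 (−0.93) and Xist (0.025) turned direction. Gli1 and Ptch1 were then called as lower, and Smo, Gli3, Pax6, Sox2, Tnc and Rgs5 gained calls. Without medial 1 and without a block, Gli1 (−1.18, not called) and Ptch1 (−0.94, called) had similar log2 fold changes. In that fit Smo, Gli3, Pax6, Sox2, Tnc and Rgs5 were not called, so their calls came with the block. Neurog2 turned under the block by number (−0.12) and Xist with limma-voom (0.57).

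Leaving out 1 library gave between 0 and 2164 calls in edgeR, between 0 and 1027 higher in medial, and between 0 and 1137 higher in lateral cortex. Where 1 lateral library was left, it was assumed to vary like the medial ones. The 0 calls without medial 2 and without lateral 2 stood beside 4035 and 2456 genes at an unadjusted p under 0.05. DESeq2 gave 3041, 2006 and 3108 without medial 1 to 3 and 2172 and 664 without lateral 1 and 2. Without medial 1 the hedgehog response list passed (0.0151, but 0.591 with an estimated correlation and 0.0977 with fry), against up to 0.920 without another library. No named gene past the threshold turned direction, which was close to fixed because each fit reused libraries of the fit that chose these genes. Of genes not called, Gli1 ranged from −1.18 to 4.91 and Ptch1 from −0.94 to 2.36, turning without medial 1. Eomes ranged from −0.23 to 0.012, Neurog2 from −0.12 to 0.21, Xist from −5.23 to 7.92 and Ddx3y from −0.36 to 10.19. Sfrp2 ranged from −0.055 to 0.39, turning without lateral 2. Of 14 lists called by camera 0 passed with an estimated correlation and 5 with fry, where basal radial glia had 0.597 and 0.107. The form with an estimated correlation passed 0 of all lists tested, so it did not separate these 14 from the others. For named genes, 374 of the values under alternatives lost their call, 11 gained 1, 14 turned direction and 1650 kept their side. The cause of these changes was not tested.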

Other observations

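The family counts, the rule for genes raised in medial library 1, both tests on tissue shared with the other medial libraries, the test on fibroblast genes and the test on hem genes were chosen after the results were seen, as were the DESeq2 counts without single libraries. The test on subpallial genes was chosen after Dlx and Gad genes were seen to differ but before its own genes were looked at, and the test on spermatid genes after the Prm1 reads were seen but before the other spermatid genes were.

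Members of some gene families passed in edgeR, where 750 of all 16229 genes were higher in medial and 827 higher in lateral cortex, and no family was tested as a whole. Of 6 tested Dmrt genes 4 were higher in medial cortex (Dmrt1, Dmrt3, Dmrta2 and Dmrtb1). Of 10 tested Wnt genes 6 were higher, Wnt2b, Wnt3a, Wnt5a, Wnt8b, Wnt9a and Wnt10a, and Wnt7b was lower. Of 6 tested genes for heparan sulfate 3-O-sulfotransferases, which modify proteoglycan chains that bind growth factors, 5 were lower in medial cortex (Hs3st2, Hs3st3a1, Hs3st3b1, Hs3st4 and Hs3st5) and 0 higher. Of 71 potassium channel and related genes 9 were lower and 4 higher, and of 74 ribosomal protein genes 0 passed with a median log2 fold change of 0.01.

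Among collagens Col4a1 and Col4a2, of vascular basement membrane, were lower in medial cortex and Col5a2, Col16a1, Col18a1 and Col28a1 higher, of 39 tested. Lateral library 2 and medial library 3 also had more genes detected, with 23124 and 23653 genes after thinning to 27406370 counts against between 20987 and 21079 in the other 3. They had 15.1 and 14.8 CPM of olfactory and vomeronasal receptor genes against at most 8.72 elsewhere.

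Of 9 listed hedgehog response genes 4, among them Gli1, Ptch1 and Hhip, were at least 2-fold higher in medial library 1 than in any of the other 4 libraries. A larger share of the hem is argued against for these 4 genes, while the other 5 were not tested for it. It would raise these genes over medial libraries 2 and 3 by no more than hem genes, but the ratios of Gli1, Ptch1 and Hhip were 137, 18.6 and 121 against 0.747 to 4.82 for 14 hem genes. In all 4 of the 4 genes the 95% lower limit was above the highest upper limit of a hem gene (8.0), where limits cover counting error only. Other medial tissue, scarce in libraries 2 and 3 or held by library 1 alone, stays open. Without library 1 the response list was lower in medial cortex with a preset correlation (camera adjusted p = 0.0151). It did not pass with an estimated one (0.591), with which 0 lists passed, or with fry (0.0977), so this decided nothing. Mesenchymal cells stay open too, as 12 of 16 fibroblast genes were at least 2-fold higher there. Fgf15 (29.0 CPM against at most 0.390) and Olig2 (16.2 against at most 1.82) were also raised in library 1. Counts of whole tissue do not separate Gli1 and Ptch1 of mesenchymal cells from those of neural cells. A candidate explanation is an animal with a transgene and raised hedgehog signalling under the wild-type label. The Prm1 3' end serves as a polyadenylation signal in some transgenes. In library 1 the 3044 Prm1 reads came with 0 reads of Prm2, Tnp1 and Tnp2, which RNA of spermatids would have brought. These 0 reads argue only against RNA of spermatids as the source. Counts per gene symbol do not show whether the Prm1 reads lie on that 3' end, as the transgene explanation needs. An earlier form of this hypothesis, tested by whether library 1 kept its medial hem genes (centred mean of 2.61 against at most −2.49 in lateral libraries), decided nothing, and neither test shows that a transgene raised the response genes.

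Of 15 tested genes of GABAergic neurons 9 were lower in medial than in lateral cortex. Subpallial tissue in the lateral dissections may account for it, since 3 of 6 tested genes of the subpallial progenitor list were lower in medial cortex, but those are Dlx1, Dlx2 and Sp9, which migrating interneurons also express. In a second set of subpallial and striatal genes that leaves such genes out, 4 were tested and 1, Drd1a, was lower, a share whose exact 95% upper limit is 80.6%, so too few of this set were tested to decide. Drd1a itself was at the threshold in edgeR (adjusted p = 0.04998) and passed in 9 of 18 alternatives. Gsx2 and Isl1 had at most 4 and 8 reads in any library. More migrating interneurons in lateral cortex, a difference of the regions themselves, stays open and was not tested.

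The count of genes that differed could also come from the greater depth of the lateral libraries. With all libraries thinned to the smallest total, 1498 genes passed against 1577, above the bound of 1051 set beforehand, which argues against depth as the whole cause. The difference in region stays open as a hypothesis that rests on 5 libraries.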
